A study of Homo sapiens with 4 samples.

How the data were processed

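Total RNA from CaSki cells, a human papillomavirus-positive cervical carcinoma line, was measured on 4 single-colour Affymetrix HG-U133 Plus 2.0 arrays. The cells carried either GFP or ZNF750, introduced by lentivirus. The titles of the samples gave 2 arrays to each group. The design text calls these biological duplicates but does not say how the cultures were made. The p-values of single genes therefore measure the spread between these arrays.

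The authors deposited 1 table of log2 values, with a row for each of 54675 probe sets and a column for each array. RMA was the only tool named, per the submitters' processing notes, and its version is not given in the sources used here. RMA corrects the background, quantile normalizes the probes across arrays and summarises each probe set on the log2 scale. It pulls low signals toward a common background, so fold changes of dim genes are understated. The deposited log2 values were not centred per gene, since each array's median lay between 5.45 and 5.51. No detection calls, scanner files or probe positions were used here. Whether a dim gene lay above background is therefore not known, and precision is limited by the number of arrays.

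Gene symbols came from the platform annotation supplied with the table. Of the probe sets that were not controls, 41091 carried 1 symbol, 1801 carried several and 11721 carried none. Of those with 1 symbol, 41037 matched a RefSeq gene by Entrez identifier, which changed 0 symbols. The 62 control probe sets were left out of the tests. Each gene was represented by the probe set with 1 symbol that had the highest mean over all 4 arrays, giving 19775 genes. For 5529 of these genes the chosen probe set ended in _s_at or _x_at, a suffix for probes that can hybridize to more than 1 transcript. No genome was used, so no coordinates are given.

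Differences are ZNF750 minus GFP on the log2 scale. They were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with 2 residual degrees of freedom. Benjamini-Hochberg adjustment covered all genes, and an adjusted p under 0.05 was called a change. Errors given with ± for genes and probe sets are limma's standard errors of the difference (n = 2 arrays per group) unless marked SD. Those of slopes come from a regression over genes and those of list medians from the spread over list members, and neither holds the spread between arrays. An exact permutation test of so few arrays cannot reach 0.05 and was not used. For 25 gene lists, limma's camera compared the members with all other genes, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. With that preset, camera's p-values rest on the spread over genes and do not measure the spread between arrays. Camera was repeated with a correlation estimated from the residuals. Each list's median was also set against 10000 random lists matched on mean expression.

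The tests, the lists and the rule for naming genes were fixed before the data were examined. The rule named ZNF750, the 15 largest rises and 15 largest falls among genes that passed and whose groups did not overlap, up to 4 members of each list with the largest absolute difference, and 15 genes fixed by name. Of the genes fixed by name, 2 are not reported here. A simulation with the same group sizes held 19775 genes, of which 200 changed. Limma recovered 2% of changes of 0.25 log2 units, 36% of changes of 0.5, 84% of changes of 1 and 100% of changes of 2. The data gave 3554 changed genes, and more changed genes loosen the adjusted threshold, so these shares do not carry over to the data. Limma made 5 false calls among 116, and camera called 0 of the lists when nothing had changed. Genes were simulated independently of each other, so this does not show how camera treats lists of correlated genes.

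The alternatives covered the variance prior, dim genes, the choice of probe set, cyclic loess, centring, the replicate number as a block, the thresholds, the set test and leaving out each array. A second quantile normalization was added after the data had been seen.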

Results

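The study asked which genes respond to ZNF750, a zinc finger protein of the squamous lineage that promotes terminal epidermal differentiation, when it is introduced into CaSki squamous carcinoma cells. Expression was compared between 2 arrays from cells carrying GFP and 2 arrays labelled ZNF750. Across the 19775 genes, the Pearson correlation was 0.9980 between the GFP arrays and 0.9977 between the ZNF750-labelled arrays. The 4 correlations between groups ranged from 0.9939 to 0.9945. The first principal component held 69.6% of the variance and separated the groups. These are correlations across genes, which are not independent replicates.

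Some array-level measures also differed between the groups. The SD over probe sets was 2.38 ± 0.018 (SD, n = 2) in the GFP arrays and 2.33 ± 0.013 (SD, n = 2) in the ZNF750-labelled arrays. The 3′ minus 5′ difference of the ACTB control probe sets, a measure of RNA integrity and labelling, was 2.92 ± 0.15 (SD, n = 2) with GFP and 3.56 ± 0.29 (SD, n = 2) with ZNF750. The same difference for GAPDH was 0.62 ± 0.0097 (SD, n = 2) and 0.82 ± 0.037 (SD, n = 2). The bacterial bioB hybridization control lay at 8.91 ± 0.051 (SD, n = 2) and 9.32 ± 0.13 (SD, n = 2). The bioC, bioD and cre controls were also higher in the ZNF750-labelled arrays, by 0.41, 0.41 and 0.23. For each measure both arrays of a group lay on one side of both arrays of the other. Whether the shift of these controls bears on the gene calls was not tested.

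**Figure D1:**
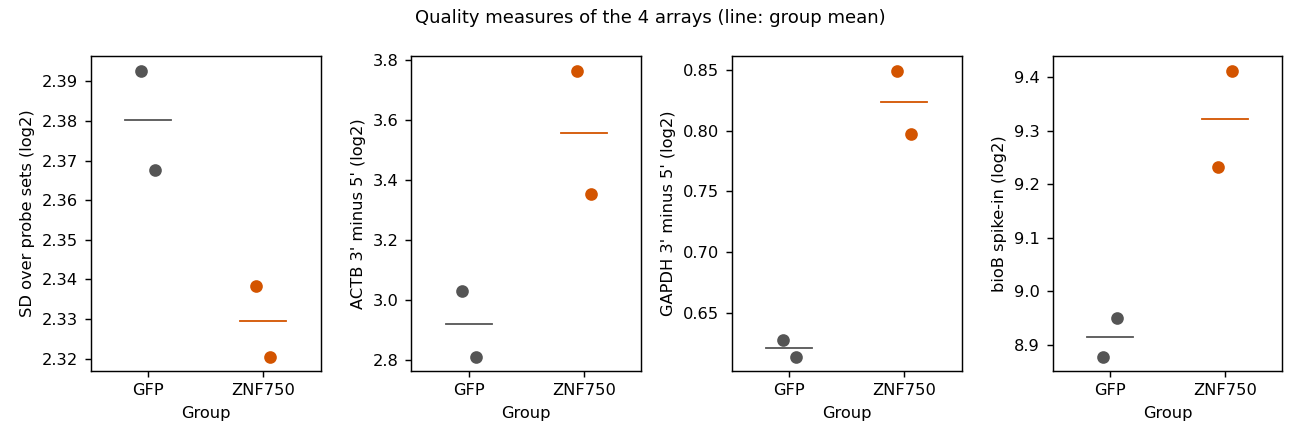
Each panel plots 1 measure on the log2 scale for the 4 arrays by group (points, arrays; lines, group means): the SD over probe sets, the 3′ minus 5′ differences of ACTB and GAPDH, and the bioB spike-in. The ZNF750-labelled arrays had the smaller SD (2.33 against 2.38) and the larger ACTB difference (3.56 against 2.92).

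The only ZNF750 probe set (219995_s_at) did not show the introduced gene. Its log2 value was 2.25 ± 0.17 (SD, n = 2) in the GFP arrays and 2.26 ± 0.041 (SD, n = 2) in the ZNF750-labelled arrays, a difference of 0.0037 ± 0.12 (limma adjusted p = 0.990). On all 4 arrays it lay near the lowest value in the table, at percentile 0.137 of the gene means. Probe sets of this array type are designed toward the 3′ end of the endogenous transcript, which an introduced coding sequence need not contain. The probe positions were not used here, so this probe set does not check the labels, and the group is called ZNF750-labelled.

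Of the 19775 genes, 1541 were higher and 2013 were lower in the ZNF750-labelled arrays (limma, adjusted p under 0.05), together 17.97% of the genes tested. Most differences were small: the median was 0.40 among the higher genes and -0.36 among the lower genes. At a log2 difference of at least 1, 53 genes were higher and 25 lower. SLPI, a secreted inhibitor of leukocyte elastase made by epithelia, rose 5.28-fold (2.40 ± 0.040 log2 units) and SERPINB4 5.19-fold (2.37 ± 0.15), sizes that were within error of each other. SERPINB4 was dim in the GFP arrays (log2 3.12), where folds are understated. SERPINB3 (3.48-fold, 1.80 ± 0.14), with SERPINB4 a squamous cell carcinoma antigen, also rose, as did SPRR1B (4.82-fold, 2.27 ± 0.13), a cornified envelope precursor. SERPINB3 and SERPINB4 are near-identical paralogs read by an _x_at and an _s_at probe set, so their signals may overlap. FLG, encoding filaggrin, rose 3.34-fold (1.74 ± 0.12), S100A9, a calprotectin subunit, 3.12-fold (1.64 ± 0.074), and the kallikrein KLK10 2.95-fold (1.56 ± 0.090). The other genes among the 15 largest rises were WAKMAR2 (3.90-fold), CCL26 (3.83-fold), ABCA1 (3.32-fold), CYP1B1 (3.31-fold), COL15A1 (3.31-fold), ZNF595 (3.29-fold), ARRDC3 (2.96-fold) and SCD (2.92-fold). ABCA1 exports cholesterol, SCD desaturates fatty acids and CYP1B1 is a cytochrome P450. Probe sets of these genes disagreed in size: KLK10 gave 0.59 without _x_at and _s_at probe sets and no longer passed (adjusted p = 0.0601), and the mean of probe sets gave 0.90 for ABCA1, 0.86 for ZNF595 and 0.70 for SCD.

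The largest fall was that of OXTR, the oxytocin receptor, which was 3.98-fold lower (-1.99 ± 0.11). IGFBP5, an insulin-like growth factor binding protein, was 3.22-fold lower (-1.69 ± 0.044). The 15 largest falls also included COL5A1 (2.80-fold lower), COL4A2 (2.57-fold lower), COL12A1 (2.57-fold lower), EFEMP1 (2.29-fold lower), VIT (2.28-fold lower) and TNC (2.26-fold lower). The remainder were CNTN1 (2.74-fold lower), RHOB (2.73-fold lower), FRMD5 (2.51-fold lower), CST6 (2.45-fold lower), CCBE1 (2.44-fold lower), SEMA5A (2.39-fold lower) and CCNB1, the mitotic cyclin B1 (2.31-fold lower). RHOB had 5 probe sets, of which 1 passed, and their mean gave -0.32 (adjusted p = 0.0723). The mean of probe sets gave -0.91 for CNTN1, -0.71 for TNC, -0.66 for COL12A1 and -0.61 for EFEMP1, and CCNB1 gave -0.69 without _x_at and _s_at probe sets.

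The counts depended on the arrays and the scaling. Without GFP replicate 1 they were 59 higher and 58 lower, without GFP replicate 2 77 and 99, without ZNF750 replicate 1 593 and 1155, and without ZNF750 replicate 2 703 and 932. Of 107 named genes that passed, 46, 50, 94 and 93 kept their call in the same order. Lower genes made up 56.6% of the calls, but 44.3% after cyclic loess, 43.4% after a second quantile normalization and 42.3% after centring on brighter genes. Without an intensity trend in limma's variance prior, 713 genes were higher and 782 lower.

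**Figure D2:**
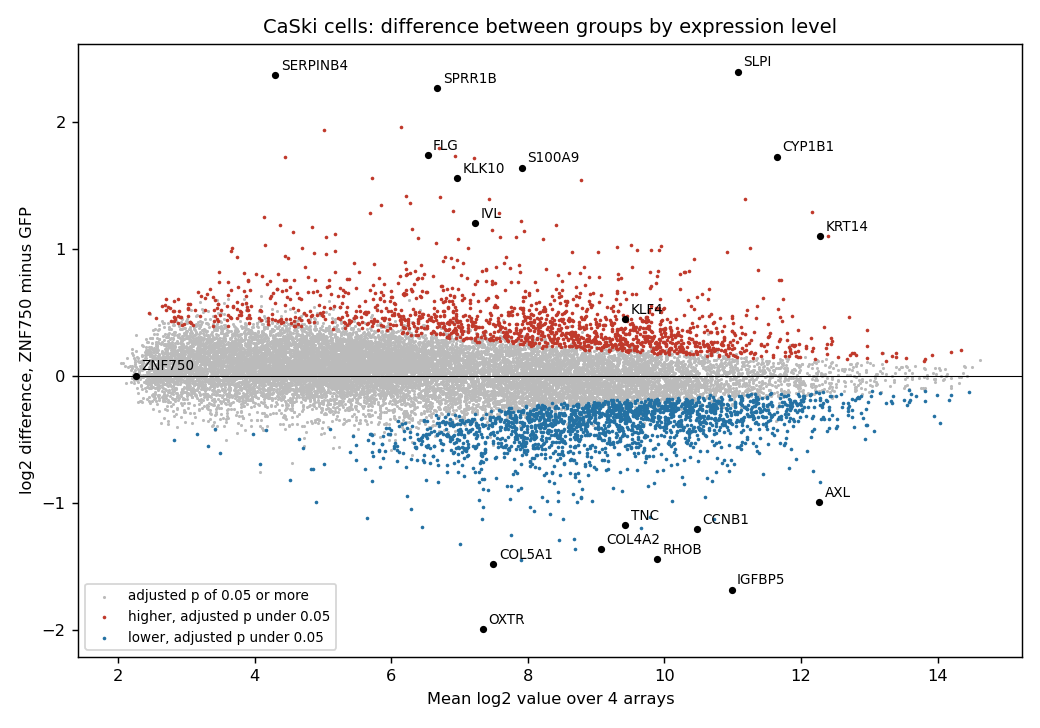
Each point is 1 of 19775 genes, with the mean log2 value over the 4 arrays on the x axis and the log2 difference, ZNF750 minus GFP, on the y axis. Red and blue points passed limma's test (1541 higher, 2013 lower), and selected genes named in the text are marked, from SLPI at 2.40 to OXTR at -1.99.

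Of 52 measured genes of epidermal differentiation and the cornified envelope, 12 rose, 2 fell and 38 did not pass. Beside SERPINB4, SPRR1B, SERPINB3 and FLG, involucrin (IVL), a cornified envelope protein, rose 2.31-fold (1.21 ± 0.085). Other classical differentiation genes did not pass: TGM1, the keratinocyte transglutaminase, differed by -0.10 ± 0.14, KRT10 by -0.16 ± 0.046 and KRT13 by 0.06 ± 0.13. KRT13 was dim in both groups (mean log2 4.06 with GFP and 4.12 with ZNF750), where differences are understated. KRT10 passed as lower with dim genes left out (adjusted p = 0.0350) and with the replicate block (0.0389). SPRR1A was 0.32 ± 0.092 higher on an _x_at probe set (adjusted p = 0.0496), and a probe set without that suffix gave -0.08. It did not pass with the mean of probe sets (0.12), over every probe set (adjusted p = 0.0618), without the intensity trend (0.0541) or with the replicate block (0.0510). Of 11 kallikreins and kallikrein inhibitors, 2 rose, KLK10 and KLK6 (1.53-fold), and 0 fell (0 also at an unadjusted limma p under 0.05). KLK10 did not pass without _x_at and _s_at probe sets (0.59, adjusted p = 0.0601), nor KLK6 without the intensity trend (0.0847) or with the replicate block (0.0663). KLK12 (0.30 ± 0.11) and KLK7 (-0.11 ± 0.12) did not pass. Of 25 genes of epidermal barrier lipid metabolism, 0 rose (2 at an unadjusted limma p under 0.05) and 2 fell, GPAT3 (-0.70 ± 0.10) and SMPD1 (-0.47 ± 0.095). SMPD1 gave 0.02 without _s_at probe sets and -0.16 with the mean of probe sets, neither passing. The cornified envelope list had a median of 0.13 (0.21 with dim genes left out, 0.074 after cyclic loess) and was higher than other genes (camera adjusted p = 0.000745; adjusted p = 0.312 with an estimated correlation). Of its 52 members, 27 were dim, and random lists of matched expression had a median of 0.065. The list's median exceeded 98.06% of them. The kallikrein and lipid lists did not pass (camera adjusted p = 0.228 and 0.904), but the kallikreins did by fry (0.0195). Adjusted over the list alone, 12 cornified envelope genes rose and 3 fell, 2 kallikreins rose and 0 fell, and 0 lipid genes rose and 2 fell. The ACTB 3′ minus 5′ difference was 0.64 larger in the ZNF750-labelled arrays, and a link between it and these genes was not tested. The number of cornified envelope genes that rose was 5 without GFP replicate 1, 6 without GFP replicate 2 and 11 with either ZNF750 replicate left out, and the 2 that fell became 0, or 1 without ZNF750 replicate 2. Of the kallikreins 2 rose without ZNF750 replicate 1 and 1 without any other array. The 2 lipid genes that fell became 0 with either GFP replicate left out and 1 with either ZNF750 replicate left out.

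Genes for the attachment of basal keratinocytes to the basement membrane were lower. Of 28 measured members, 18 fell, 3 rose and 7 did not pass, with a median of -0.42. The collagen IV chains COL4A2 (-1.36 ± 0.065), COL4A1 (-0.99 ± 0.087) and COL4A5 (-0.95 ± 0.094) had the largest falls. ITGB4, the integrin chain of hemidesmosomes, fell by 0.61 on the log2 scale (SE 0.055). COL4A5 and ITGB4 were read by _s_at probe sets. Their brightest probe sets without _x_at and _s_at gave 0.13 and 0.42, neither of which passed. ITGB4 had 5 probe sets, of which 2 passed as lower and 0 as higher in a fit over all probe sets. With the mean of probe sets COL4A5 gave -0.41, and ITGB4 gave -0.22 and did not pass (adjusted p = 0.116). The 3 members that rose were the basal keratins KRT14 (2.15-fold, 1.10 ± 0.035) and KRT5 (1.18-fold, 0.24 ± 0.032), intermediate filament proteins, and KRT15 (0.77), named here after its value was seen. KRT5 did not pass without the intensity trend (0.0865). The list was lower than other genes (camera adjusted p = 1.75e-07; adjusted p = 0.312 with an estimated correlation), and 19 members fell and 3 rose adjusted over the list alone. Beside this fall, the ACTB 3′ minus 5′ difference was 0.64 larger. The number of genes that fell was 3 without GFP replicate 1, 4 without GFP replicate 2 and 16 with either ZNF750 replicate left out, and 2 or 3 rose each time.

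Transcription factors of the squamous lineage were higher as a group: 12 of 34 rose, 1 fell and 21 did not pass, with a median of 0.23 (0.12 with the mean of probe sets). ELF3, an epithelial ETS factor, rose 2.22-fold (1.15 ± 0.082), CEBPB 1.69-fold (0.76 ± 0.039), KLF5 1.56-fold (0.64 ± 0.081) and BCL11B 1.54-fold (0.63 ± 0.096). KLF4, a differentiation factor, rose 1.37-fold (0.45 ± 0.061) and GRHL3 1.34-fold (0.43 ± 0.11). With the mean of probe sets BCL11B (0.29, adjusted p = 0.0537) and KLF4 (0.23, 0.0833) did not pass, and GRHL3 did not pass over every probe set (0.0519), after cyclic loess (0.0560) or after a second quantile normalization (0.0536). SOX2 differed by -0.02 ± 0.11. HOPX (-0.53), the member that fell, is named here after its value was seen, and gave 0.47 without _x_at and _s_at probe sets and -0.02 with the mean of probe sets, neither passing. The list passed (camera adjusted p = 0.000364; adjusted p = 0.312 with an estimated correlation), and 16 members rose and 2 fell adjusted over the list alone. In the same arrays the ACTB 3′ minus 5′ difference was 0.64 larger. Only 2 members rose with either GFP replicate left out, 6 without ZNF750 replicate 1 and 7 without ZNF750 replicate 2. Of 19 ZNF750 partners and corepressors, 5 rose and 2 fell, and the list did not pass (camera adjusted p = 0.290), although after cyclic loess (0.0243) and a second quantile normalization (0.0293) it did. PHF21A (0.59 ± 0.068), GSE1 (0.54 ± 0.076) and RCOR2 (0.42 ± 0.077) rose, and PHF21A gave -0.19 without _s_at probe sets. The mean of probe sets gave 0.24 for GSE1 and 0.18 for PHF21A, which then did not pass. When adjusted over the list alone, 6 partners rose and 3 fell, and over all genes 0 rose and 0 fell with either GFP replicate left out, 3 rose and 1 fell without ZNF750 replicate 1, and 4 rose and 1 fell without ZNF750 replicate 2.

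Of 30 genes of desmosomes and tight junctions, 10 rose, 3 fell and 17 did not pass, with a median of 0.12. The tight junction genes CLDN1 (1.97-fold, 0.98 ± 0.079), CLDN7 (1.66-fold, 0.73 ± 0.054) and OCLN (1.56-fold, 0.64 ± 0.076) rose, as did JUP, encoding plakoglobin (1.61-fold, 0.69 ± 0.043). OCLN gave 0.34 with the mean of probe sets. The list passed narrowly (camera adjusted p = 0.0379; adjusted p = 0.512 with an estimated correlation) and did not pass with the mean of probe sets (median 0.053, 0.410), on ranks (0.0931), by fry (0.072), with the replicate block (0.0549), without GFP replicate 2 (0.159) or without ZNF750 replicate 1 (0.158). With p-values adjusted over the list alone, 12 members rose and 4 fell, in arrays whose ACTB 3′ minus 5′ difference was 0.64 larger. The junction genes that rose numbered 2 with either GFP replicate left out, 4 without ZNF750 replicate 1 and 6 without ZNF750 replicate 2, and those that fell 0, 2 and 2.

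Mesenchymal and motility genes moved both ways: 18 of 47 fell, 6 rose and 23 did not pass, with a median of -0.10. COL5A1 (-1.48 ± 0.10), TNC, encoding tenascin C (-1.18 ± 0.058), and AXL, a receptor tyrosine kinase (-0.996 ± 0.043), fell, whereas the collagenase MMP13 rose (0.99 ± 0.17). TNC gave -0.71 with the mean of probe sets. The list was lower than other genes (camera adjusted p = 0.0129; adjusted p = 0.312 with an estimated correlation) but not with the mean of probe sets (median -0.031, 0.159), on ranks (0.348) or without GFP replicate 2 (median -0.032, 0.0514). Its median was also -0.028 without _x_at and _s_at probe sets, -0.053 without ZNF750 replicate 1, -0.061 after cyclic loess and -0.23 with dim genes left out, where it passed. Adjusted over the list alone, 18 members fell and 11 rose, again beside an ACTB 3′ minus 5′ difference 0.64 larger. Of the mesenchymal genes, those that fell numbered 3 without GFP replicate 1, 4 without GFP replicate 2 and 17 with either ZNF750 replicate left out. Those that rose numbered 0 with either GFP replicate left out, 2 without ZNF750 replicate 1 and 4 without ZNF750 replicate 2. Of 28 YAP/TEAD and TGF-beta targets, 10 fell and 5 rose (camera adjusted p = 0.00908; adjusted p = 0.312 with an estimated correlation). This call ended after cyclic loess (0.0531), after a second quantile normalization (0.0688) and with dim genes left out (0.0899), and centring on brighter genes moved the median from -0.10 to -0.056. AXL and LTBP2 (-0.62 ± 0.067) fell and ID2 (0.63 ± 0.10) and ID3 (0.59 ± 0.057) rose. When adjusted over the list alone, 12 fell and 6 rose. Over all genes, 1 fell and 0 rose with either GFP replicate left out, and 8 fell and 3 rose with either ZNF750 replicate left out.

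The Wnt and Notch lists did not pass (camera adjusted p = 0.287 and 0.847). Of 26 Wnt genes 0 rose (2 at an unadjusted limma p under 0.05) and 5 fell, among them TCF7L1 (-0.62 ± 0.082), WNT7A (-0.60 ± 0.077), LGR4 (-0.58 ± 0.14) and WNT5A (-0.50 ± 0.12), and LGR4 gave 0.14 without _s_at probe sets, -0.11 with the mean of probe sets and an adjusted p of 0.0982 without the intensity trend. The Wnt median (0.011) and mean (-0.079) differed in sign. Of 24 Notch genes 4 rose and 5 fell: the Fringe genes LFNG (-0.68 ± 0.058) and MFNG (-0.65 ± 0.10) and the receptor NOTCH2 (-0.38 ± 0.057) fell, and HES2 rose (0.54 ± 0.070). MFNG gave -0.05 without _x_at and _s_at probe sets (adjusted p = 0.857), and the mean of probe sets gave -0.38 for MFNG and -0.45 for LFNG. The Notch median (0.035) and mean (-0.0078) also differed in sign. With p-values adjusted over the list alone, 5 Wnt genes fell and 0 rose, and 6 Notch genes fell and 4 rose. With either GFP replicate left out, 0 genes of both lists fell or rose, and with either ZNF750 replicate left out 3 Notch genes rose. Then 4 Wnt and 5 Notch genes fell without ZNF750 replicate 1, and 2 and 3 without ZNF750 replicate 2. The ACTB 3′ minus 5′ difference was 0.64 larger beside these changes too.

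Genes of mitosis were lower and genes of DNA replication were not. Of 53 G2/M genes, 38 fell, 0 rose and 15 did not pass, with a median of -0.32. CCNB1 (2.31-fold lower, -1.21 ± 0.071), the spindle genes DLGAP5 (2.16-fold lower, -1.11 ± 0.054) and KIF23 (2.04-fold lower, -1.03 ± 0.080), and the chromosomal passenger gene CDCA8 (1.84-fold lower, -0.88 ± 0.066) had the largest falls. Without _x_at and _s_at probe sets KIF23 gave -0.24 and did not pass (adjusted p = 0.0918), and CCNB1 gave -0.69. KIF23 gave -0.64 with the mean of probe sets. The list was the lowest by camera's p among the 25 (adjusted p = 3.06e-24; adjusted p = 0.312 with an estimated correlation), and its median lay below all 10000 random lists of matched expression. Adjusted over the list alone, 39 members fell and 0 rose, and at an unadjusted limma p under 0.05 0 rose. The ACTB 3′ minus 5′ difference of the same arrays was 0.64 larger. G2/M genes that fell numbered 12 with either GFP replicate left out, 34 without ZNF750 replicate 1 and 29 without ZNF750 replicate 2. Of 52 G1/S and replication genes, 16 rose, 1 fell and 35 did not pass, with a median of 0.068. DTL (0.61 ± 0.054), the licensing factor CDT1 (0.54 ± 0.047) and CCNE2, encoding cyclin E2 (0.41 ± 0.069), rose, and CCND1, encoding cyclin D1, fell (-0.52 ± 0.048). CCNE2 did not pass with the mean of probe sets (0.12, adjusted p = 0.263) or without the intensity trend (0.0598). This list passed (camera adjusted p = 0.00895; adjusted p = 0.512 with an estimated correlation) but not without GFP replicate 2 (median 0.036, 0.159), by fry (0.0949), with the mean of probe sets (0.109) or without _x_at and _s_at probe sets (0.145). Its median was 0.13 after cyclic loess and 0.11 without GFP replicate 1. When adjusted over the list alone, 18 replication genes rose and 1 fell. Over all genes, 1 rose and 0 fell with either GFP replicate left out, 7 rose and 1 fell without ZNF750 replicate 1, and 6 rose and 1 fell without ZNF750 replicate 2.

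Of 28 p53 targets, 10 rose, 3 fell and 15 did not pass (camera adjusted p = 0.290; 0.0215 by fry). The cyclin-dependent kinase inhibitor CDKN1A rose 1.75-fold (0.80 ± 0.048), TP53INP1 1.85-fold (0.89 ± 0.10) and RRM2B by 0.68 ± 0.060 log2 units, while CCNG1 fell (-0.60 ± 0.052). TP53INP1 gave 0.38 with the mean of probe sets. MYC fell by 0.20 on the log2 scale (SE 0.047), but not past the threshold after cyclic loess (-0.13, adjusted p = 0.104), centring on brighter genes (0.0942), a second quantile normalization (0.0929) or without the intensity trend (0.142). With p-values adjusted over the list alone, 10 targets rose and 4 fell, and over all genes 2 rose without GFP replicate 1, 1 without GFP replicate 2, 5 without ZNF750 replicate 1 and 7 without ZNF750 replicate 2. The targets that fell numbered 0, 1, 3 and 3 in that order. These targets, too, moved beside an ACTB 3′ minus 5′ difference 0.64 larger.

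Interferon-response genes were higher: 15 of 45 rose, 2 fell and 28 did not pass, with a median of 0.24. SAMD9 rose 1.99-fold (0.99 ± 0.061), IFI6 1.67-fold (0.74 ± 0.074), IFIT2 by 0.68 ± 0.088 log2 units and OAS1 1.58-fold (0.66 ± 0.18). OAS1 did not pass with the mean of probe sets (0.47, adjusted p = 0.0737), over every probe set (0.0535), without _x_at and _s_at probe sets (0.0501), without the intensity trend (0.0968) or with the replicate block (0.0629), and IFIT2 gave 0.42 with the mean of probe sets. The list passed (camera adjusted p = 6.19e-05; adjusted p = 0.497 with an estimated correlation) but not by fry (0.0588), and 16 members rose and 2 fell adjusted over the list alone. The ACTB 3′ minus 5′ difference was 0.64 larger in these arrays. Interferon genes that rose numbered 1 with either GFP replicate left out, 8 without ZNF750 replicate 1 and 12 without ZNF750 replicate 2, and 1 fell without ZNF750 replicate 1 and 0 without any other array. Of 31 NF-kB and inflammatory cytokine genes, 12 rose and 4 fell. The median of 0.17 was 0.091 without GFP replicate 1, 0.30 without GFP replicate 2, 0.11 with the mean of probe sets and 0.44 with dim genes left out, and the list passed each time. PTGS2, encoding cyclooxygenase, rose 2.12-fold (1.08 ± 0.079), SOD2 2.05-fold (1.03 ± 0.053) and IL1B 1.75-fold (0.81 ± 0.074), and IL18 was 1.99-fold lower (-0.995 ± 0.17). The list passed (camera adjusted p = 0.00114; adjusted p = 0.312 with an estimated correlation). Adjusted over the list alone, 13 rose and 4 fell. Over all genes, 2 rose and 0 fell with either GFP replicate left out, and 10 rose and 3 fell with either ZNF750 replicate left out. Of 28 EGFR ligand, AP-1 and immediate early genes, 6 rose and 6 fell (camera adjusted p = 0.660). ATF3 rose 2.33-fold (1.22 ± 0.072) and JUND (0.71 ± 0.050) and PHLDA1 (0.53 ± 0.037) rose, whereas EGR1 fell (-0.74 ± 0.078). ATF3 did not pass without _x_at and _s_at probe sets (0.18, adjusted p = 0.316), nor JUND with the mean of probe sets (0.14, 0.302), which gave 0.58 for ATF3 and 0.34 for PHLDA1. This list's median (-0.028, and 0.031 after cyclic loess) and mean (0.078) differed in sign. When adjusted over the list alone, 10 rose and 7 fell, and over all genes 0 fell with either GFP replicate left out, 2 without ZNF750 replicate 1 and 4 without ZNF750 replicate 2. Those that rose numbered 3 without GFP replicate 1, 4 without GFP replicate 2 and 5 with either ZNF750 replicate left out.

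Hypoxia and glycolysis genes were higher: 13 of 32 rose, 2 fell and 17 did not pass, with a median of 0.15. The members with the largest rises are known as hypoxia-responsive genes or as an isozyme of glycolysis: NDRG1 (2.46-fold, 1.30 ± 0.049), ENO2 (2.01-fold, 1.01 ± 0.080), BNIP3 (1.78-fold, 0.83 ± 0.042) and ANGPTL4 (1.58-fold, 0.66 ± 0.066). The list passed (camera adjusted p = 0.000222; adjusted p = 0.312 with an estimated correlation). With p-values adjusted over the list alone, 14 rose and 3 fell, beside an ACTB 3′ minus 5′ difference 0.64 larger. Over all genes, 2 rose without GFP replicate 1, 4 without GFP replicate 2 and 9 with either ZNF750 replicate left out, and 1 fell without ZNF750 replicate 2 and 0 without any other array. Among 30 genes of unfolded protein and amino acid stress, 9 rose and 8 fell (camera adjusted p = 1.000; 0.0381 by fry). DDIT4 (0.92 ± 0.051), CEBPB and, with the limit given above, ATF3 rose, and HSPA5, the chaperone BiP, fell (-0.77 ± 0.067). That list's median (-0.029, and 0.037 after cyclic loess) and mean (0.070) differed in sign. Of 18 cholesterol biosynthesis genes 1 rose, SREBF2 (0.30 ± 0.075), and 3 fell, PMVK (-0.33 ± 0.059), NSDHL (-0.24 ± 0.062) and LSS (-0.22 ± 0.054), with a camera adjusted p of 0.0630. The list passed with the mean of probe sets (0.00621), with the replicate block (0.0414) and by fry (0.0269). With the mean of probe sets LSS (-0.099) and SREBF2 (0.12) did not pass and NSDHL gave -0.38. NSDHL and LSS did not pass after cyclic loess (0.0723 and 0.0730), and none of the 4 genes passed without the intensity trend. Of 25 NRF2 targets 3 rose and 6 fell (camera adjusted p = 0.348), among them PGD (-0.54 ± 0.054) and TALDO1 (-0.38 ± 0.037), enzymes of the pentose phosphate pathway, and AKR1C1 (0.39 ± 0.052). PGD gave -0.17 with the mean of probe sets (adjusted p = 0.141) and AKR1C1 0.12 without _x_at and _s_at probe sets (0.56), neither passing, and AKR1C1 gave 0.26 with the mean of probe sets. AKR1B10 (0.43 ± 0.13) did not pass, but did with the mean of probe sets (0.0464) and after centring on brighter genes (0.0299). Adjusted over the list alone, 10 stress genes rose and 10 fell, 1 cholesterol gene rose and 3 fell, and 5 NRF2 targets rose and 6 fell. With either GFP replicate left out, 0 cholesterol genes and 0 NRF2 targets passed and 3 stress genes rose. Stress genes that fell numbered 0 without GFP replicate 1 (HSPA5 had an adjusted p of 0.0557), 1 without GFP replicate 2, 6 without ZNF750 replicate 1 and 3 without ZNF750 replicate 2. Without ZNF750 replicate 1, 0 cholesterol genes passed and 3 NRF2 targets rose and 4 fell; without ZNF750 replicate 2, 1 cholesterol gene fell and 1 NRF2 target rose and 3 fell.

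Few markers of fibroblasts, leukocytes, endothelium and melanocytes passed. Of 16 fibroblast markers 1 fell, FAP (-0.78 ± 0.20), and 0 rose. COL1A2 (0.48 ± 0.16), POSTN (0.39 ± 0.14) and COL3A1 (0.34 ± 0.16) did not pass. COL1A2 did pass as higher with the mean of probe sets (0.47, adjusted p = 0.0196), after centring on brighter genes (0.0362) and with the replicate block (0.037). Of 16 leukocyte markers 0 passed, CD8A (0.38 ± 0.13) having the largest measured difference, and of 14 endothelial and melanocyte markers 0 passed, KDR (-0.18 ± 0.11) having the largest. After centring on brighter genes CD8A (adjusted p = 0.0486) and CD79A (0.30, 0.0495) passed as higher. At an unadjusted limma p under 0.05, 3 leukocyte markers and 2 fibroblast markers were higher, and 0 endothelial and melanocyte markers differed. With 1 array left out, FAP passed without ZNF750 replicate 1 and did not pass without any other array, nor without the intensity trend (0.116). Of 24 glandular and columnar epithelium markers, 5 rose and 2 fell, with a median of 0.14 that exceeded 98.93% of matched random lists (0.079 without GFP replicate 1, 0.083 without ZNF750 replicate 2): LCN2, encoding lipocalin 2 (2.63-fold, 1.39 ± 0.042), ELF3 and MUC16 (1.82-fold, 0.86 ± 0.13) rose, and KRT7 fell (-0.38 ± 0.035), although KRT7 gave 0.14 without _s_at probe sets and -0.12 with the mean of probe sets, neither passing. None of these 4 lists passed camera, with adjusted p of 0.855, 0.290, 0.855 and 0.184 in the order given. When adjusted over the list alone, 0 markers of the first 3 lists passed, and 5 glandular markers rose and 2 fell. Of the glandular markers 2 rose with either GFP replicate left out and 3 with either ZNF750 replicate left out, 0 fell without GFP replicate 2 and 1 without GFP replicate 1, and without _x_at and _s_at probe sets that list passed (0.0258).

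**Figure D3:**
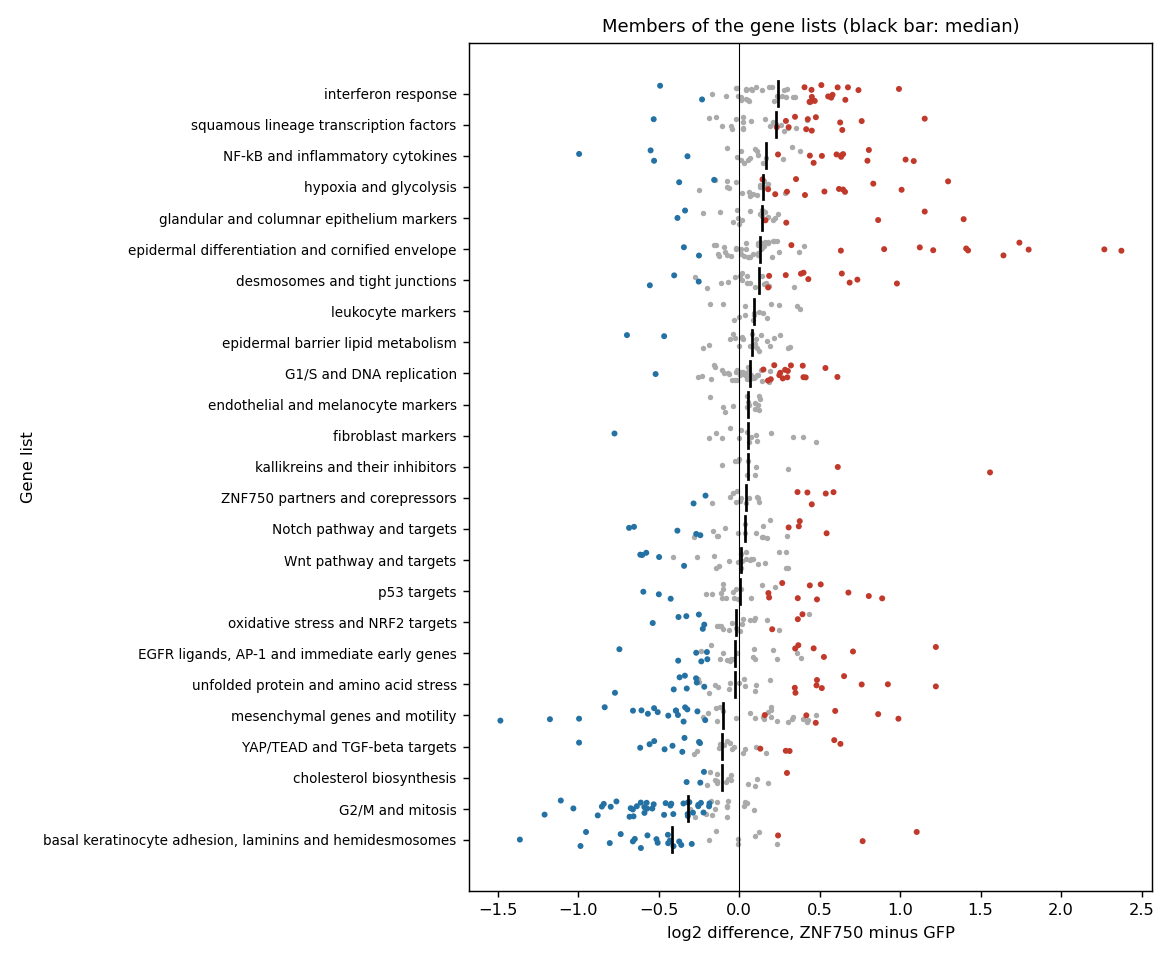
Each point is a gene of 1 of the 25 lists (y axis), placed at its log2 difference, ZNF750 minus GFP (x axis). Coloured points passed limma's test, grey points did not, and black bars are list medians, which run from -0.42 for basal adhesion and -0.32 for G2/M to 0.24 for the interferon response.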

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

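The test of single misassigned arrays, that of the share of cycling cells and that of the reach of the ZNF750 probe set were chosen only after the results they bear on had been seen. One signal lay in data outside the comparisons: of 11721 probe sets without a gene symbol, 747 passed limma's test over all probe sets, 391 higher and 356 lower in the ZNF750-labelled arrays. The largest rises were those of 213680_at (2.29 ± 0.16) and 214580_x_at (1.86 ± 0.052), and the largest falls those of 243555_at (-1.21 ± 0.12) and 202628_s_at (-1.15 ± 0.046). Of 1801 probe sets with several symbols, 98 were higher and 199 lower.

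The ZNF750 probe set lay near the floor on all 4 arrays. A single array of the wrong group is argued against, since the lowest correlation within a group (0.9977) exceeded the highest between groups (0.9945). This holds only if shared processing did not set the correlations, because the array-level measures split the arrays in the same way. That the probe set does not read the introduced transcript cannot be told apart from a lack of over-expression: its difference was 0.00367, and the probe positions that would decide were not used here. An exchange of both group names also stays open.

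Values were spread more narrowly in the ZNF750-labelled arrays, with dim genes higher and bright genes lower (medians of 0.088 among the dimmest and -0.060 among the brightest 10% of genes). A technical drift between arrays stays open, since the difference also sloped on mean level within groups. The slope was -0.0235 ± 0.00068 between groups, and replicate 2 minus replicate 1 gave -0.0114 ± 0.00045 within GFP and -0.0103 ± 0.00047 within ZNF750. The sign within groups follows the replicate numbers, so only the size bears on drift, and it was smaller than between groups. RNA integrity stays open, because the ACTB 3′ minus 5′ difference was 0.635 larger with ZNF750, by more than the largest gap between replicates (0.411), yet it was smaller in the narrower array of each group. No test separated either from an effect of ZNF750 on the range of expression.

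G2/M genes were lower in the ZNF750-labelled arrays. The drift of bright genes as the whole cause is argued against, since after cyclic loess the list's median was still -0.255, and 0 of 10000 random lists of matched expression lay as low. A 3′ to 5′ bias predicts a higher G2/M median in the array of each group with the smaller control difference, and stays open: replicate 2 minus replicate 1 gave -0.034 in GFP and -0.0351 in ZNF750, but this sets 1 array against 1, and matched random lists moved the same way (medians of -0.017 and -0.020). A smaller share of cycling cells as the whole cause is argued against only if replication genes follow that share, which was not tested in these cells. Their median was 0.068 ± 0.035 (0.13 after cyclic loess, 0.036 to 0.113 with 1 array left out), an error that holds no spread between arrays. Otherwise, and as part of the cause, a smaller share stays open. Replication-dependent histones, listed only after the gene differences had been seen, had a median of -0.10. Of these 30 genes, 4 fell and 1 rose. A shift in the distribution of cells over the cycle, by ZNF750 or by culture density, may remain and was not tested.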

How the results depend on the processing

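The second quantile normalization was chosen after seeing the data. Counts of higher and lower genes moved from 1541 and 2013 to 713 and 782 without the intensity trend, and to 53 and 25 at a log2 difference of at least 1. Centring on brighter genes gave 2508 higher genes. Leaving out 1 array gave 59 to 703 higher and 58 to 1155 lower genes, with 1 residual degree of freedom and the lone array assumed to vary like the other group. Of the main calls, 1492 higher and 1690 lower genes kept their call after cyclic loess, which shifted the median of all genes from 0.036 to 0.031. The number of lists called fell from 11 to 0 with an estimated correlation, where the medians (0.13 for the cornified envelope, -0.42 for basal adhesion, 0.23 for squamous transcription factors, -0.32 for G2/M) are the same and the adjusted p was 0.312 for each. Camera then uses the 2 residual degrees of freedom, and 2 lists had an unadjusted p under 0.05. Camera on ranks called 9 lists and fry, which does not compare a list with other genes, 12. The lowest within-group and highest between-group correlations were 0.9973 and 0.9889 without dim genes and 0.9968 and 0.9937 over all probe sets. Without _x_at and _s_at probe sets COL4A5 (0.13), ITGB4 (0.42), KRT7 (0.14), LGR4 (0.14), PHF21A (-0.19), SMPD1 (0.020) and SPRR1A (-0.084) changed sign, none passing; the cause was not tested. With the replicate block, 1676 genes were higher and 2291 lower, sharing 1432 and 1954 with the main calls, the desmosome list no longer passed (0.0549) and cholesterol biosynthesis did (0.0414). The deviations of same-numbered arrays correlated at 0.161 across genes, which does not establish a pairing with so few arrays. Of 107 named genes that passed, 39 passed under every alternative in which they were tested. Over 1725 gene and setting pairs, 195 lost the call, 9 gained it and 7 reversed. Dim signal limits the rest: 6954 genes lay below the median probe set level of 5.47.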

Other observations

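The lists in this part were written after the gene differences had been seen, and each except the histones was tested without the genes that prompted it. Of 37 collagen chains, 9 fell, 2 rose and 26 did not pass. The basement membrane collagens COL4A1, COL4A2, COL4A4 (-0.42 ± 0.089), COL4A5 and COL4A6 (-0.41 ± 0.093), the fibrillar COL5A1 and the fibril-associated COL12A1 fell, as did COL16A1 (-0.62 ± 0.095) and COL7A1 (-0.65 ± 0.070), the anchoring fibril collagen. COL4A5 was read by an _s_at probe set, and without such probe sets it gave 0.13. COL4A4 (-0.11) and COL4A6 (-0.18) did not pass with the mean of probe sets. COL15A1 rose (1.73 ± 0.17), and COL11A1 (0.52 ± 0.14), dim in the GFP arrays (log2 2.86), passed narrowly. The limma call of COL11A1 ended over every probe set (adjusted p = 0.0525) and without _x_at and _s_at probe sets (0.0505). It also ended with the mean of probe sets (0.101), without the intensity trend (0.0788) and with any array left out. Of 30 linker and core histone genes, listed as replication-dependent, 4 fell and 1 rose, with a median of -0.10. No gene was removed from this list, so no test of it is reported here. H2AC6 (-0.54 ± 0.077) fell and H2BC12 (0.24 ± 0.041) rose, H2BC12 not without the intensity trend (0.0946). The ACTB 3′ minus 5′ difference was 0.64 larger beside all changes in this part.

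For the hypotheses below, each raised by large changes, no test passed beyond the genes noticed. A general rise of liver X receptor targets was prompted by ABCA1, SCD and MYLIP (1.19 ± 0.066, but 0.24 and not passing without _x_at and _s_at probe sets), and the other 14 gave a limma camera p of 0.689 (adjusted p = 0.689), with NR1H3, the receptor gene itself, higher (0.79 ± 0.12) and TMEM135 (-0.42 ± 0.085), MMAB (-0.39 ± 0.084) and ELOVL5 (-0.23 ± 0.044) lower. With the mean of probe sets these 3 gave -0.07, -0.10 and -0.01 and did not pass, and TMEM135 gave 0.29 without _s_at probe sets. MYLIP had 6 probe sets, of which 4 passed as higher and 0 as lower in a fit over all probe sets. A rise of aryl hydrocarbon receptor targets was prompted by CYP1B1, and the other 10 gave a limma camera p of 0.285 (adjusted p = 0.380), with TIPARP (0.37 ± 0.049) and CYP1A2 (0.55 ± 0.088) higher and NQO1 (-0.33 ± 0.037) lower. CYP1A2 did not pass with the mean of probe sets (0.33, adjusted p = 0.0657), nor NQO1 without the intensity trend (0.0544). A general fall of collagens without the 5 genes noticed gave a limma camera p of 0.243 (adjusted p = 0.380), and 0.0575 unadjusted after cyclic loess. Of the genes named only in this part, MYLIP alone passed with either GFP replicate left out. COL4A4, COL4A6 and ELOVL5 did not pass with either ZNF750 replicate left out, H2BC12, MMAB and TMEM135 not without ZNF750 replicate 2, and COL4A6, ELOVL5, MMAB and TMEM135 not without the intensity trend.

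The arrays can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The real split gave 3554 changed genes and was the 1 split with as many, the highest of the others giving 0 by limma (271 at an unadjusted p under 0.05, against 6291). Each other split mixes the groups, so the difference between groups widens its spread and makes few calls likely. The contrast is therefore no measure of chance.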
